A study of Mus musculus with 2 samples.

How the data were processed

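The 2 adrenal gland libraries from 14-day-old male B6CASTF1/J mice were analysed, both of 1 group, per the labels. The labels name biological replicates 1 and 2 with separate tissue samples under 1 donor record, 300 ng of starting RNA, a directional library kit and ERCC spike-ins for ribosomal RNA reduced libraries. Values describe the spread between these samples. The labels name pools with the wording 3x Males, which they do not explain, so the number of animals per library is not known. In the sample descriptions both libraries carry the same pool number of males, whereas the tissue descriptions give them different pool numbers, so the SD may not span separate animals.

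Expected counts and TPM per gene and per transcript were deposited by the authors, quantified from transcriptome alignments against mm10 with GENCODE annotation M21, per the deposited file list. The column names, per the file headers, are those that RSEM writes, and these are called RSEM values; the tool versions and the aligner are not given in the sources used here. The gene tables deposited by the authors also hold FPKM, which was not used in any result, posterior mean TPM, and credibility bounds of TPM, a signal that does not add up to a fixed total, per the file headers. Estimated counts and TPM per transcript of a second quantification were made from the 2 read files of each library, per the deposited file list; their column names are those of kallisto, per the file headers, and they were summed here to genes. The percent of each gene's TPM on each transcript is a column of the deposited transcript tables; it was recomputed here from TPM. Effective length, a further deposited column with another unit (bases), was 99 bases below the length for 99.99% of genes longer than 200 bases in the RSEM values, per the file headers, and a median of 324.1 and 320.1 bases below it in the kallisto values of replicates 1 and 2. This difference bears most on short RNAs, whose TPM depends on it. Reads of CAST alleles were aligned to the mm10 reference, and the effect was not measured.

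TPM was computed by the authors over all entries, spike-ins included, per the file headers. Gene names, types and coordinates were taken from the GENCODE M21 annotation. Nuclear protein-coding genes were those typed as protein-coding outside the mitochondrial chromosome, 22015 in all, and 86 genes had no entry in the kallisto values and were left out of comparisons with them. Of 291 distinct genes in 27 lists fixed before the data were examined, 289 were found in the annotation.

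Detected genes had at least 1 TPM in both libraries. Ratios of genes and lists were taken per library and given as mean and SD (n = 2). The lists covered steroid synthesis, the cortical zones, the X-zone, cholesterol, catecholamines, chromaffin granules, transcription factors, glia, capsule, endothelium, macrophages, lymphocytes, erythroid cells, fat, kidney, liver and pancreas, muscle, proliferation, immediate early genes, heat shock, glucocorticoid response, the clock, imprinted genes, Y-linked genes with Xist, mitochondrial messengers and abundant RNAs without poly(A) tails. For each list with at least 3 members at 1 TPM or more in either library, the median difference in log2(TPM + 1), replicate 2 minus replicate 1, was placed among 10000 random lists of the same size drawn in 20 bins of mean expression from nuclear protein-coding genes. Such a percentile describes these libraries and is no test of a population. Lists of 30 hepatocyte genes, 10 lymph node genes and the globins were added after the data were examined. Folds against a library with 0 counts used a floor of 3 counts. Shares of single libraries carry 95% exact binomial intervals.

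The biological coefficient of variation was the square root of the common dispersion from edgeR 4.0.16 in R 4.3.3, with an intercept-only model, TMM factors, RSEM expected counts rounded to whole numbers and at least 10 counts in both libraries. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. A chi-square of the rounded counts over genes gave 54.5 per degree of freedom, so their difference exceeded counting noise, which does not tell biological from technical spread. They were counted as 2 samples because the labels call them biological replicates. Tested on simulated counts for 16981 genes with a coefficient of 0.15, the dispersion step returned 0.151, and 0.182 with 200 genes raised 4-fold. Tested on simulated TPM of the 22015 nuclear protein-coding genes, lists of 10 genes raised or lowered 4-fold lay at percentiles 100 and 0, and 4% of 100 unchanged lists lay outside the central 95%. Among 8314 simulated genes with a mean of at least 5 TPM, 100% of 200 genes changed 4-fold and 11 unchanged genes lay beyond 2-fold. The simulated genes varied independently with a coefficient of 0.15, against 0.285 in the libraries. These rates therefore do not carry over to the libraries or to lists whose genes vary together.

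Genes were named by a rule set before the data were examined. It took the 4 members of each list with the highest mean TPM, every member of the steroid synthesis, X-zone, catecholamine and Y-linked lists, and the 10 most abundant nuclear protein-coding genes. Among nuclear protein-coding genes with a mean of at least 5 TPM it took the 8 largest and 8 smallest replicate ratios and the 5 largest RSEM to kallisto ratios each way, genes at 0 by kallisto being ranked by RSEM TPM; last came the 5 most abundant lincRNA genes. Some genes that the rule takes are not reported here by name, though they count in list values. Alternatives covered the minimum level, pseudocount, scaling (TMM, spike-ins, nuclear protein-coding genes), list summary, posterior mean TPM, kallisto in place of RSEM, and leaving out each replicate. A value with an SD was taken as moved when it shifted by 1 SD or more, a count beyond 1.5 times, a correlation beyond 0.01, the coefficient of variation beyond 1.1 times, and a list median by the SD of its random lists or more.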

Results

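Total RNA from the adrenal glands of 14-day-old male mice was measured by RNA sequencing in 2 libraries. The mice were B6CASTF1/J, first-generation offspring of a cross between C57BL/6J and CAST/EiJ inbred strains. The adrenal gland has a cortex that makes steroid hormones and a medulla whose chromaffin cells make catecholamines. Per the labels, the libraries are biological replicates 1 and 2 of a single group, from separate tissue samples, and each was started from 300 ng of RNA. The labels number the pool of males alike for both libraries in one field and differently in another, so the SD may or may not span separate animals. With 1 group there was no contrast between conditions, and no p-value is given. The values describe the tissue samples as collected at this age, with any other tissue they held, and the spread between the replicates. The replicate 1 library held 32963248 expected counts and the replicate 2 library 36260745. Nuclear protein-coding genes took 17154352 and 19024838 of these. At least 1 TPM (transcript abundance corrected for gene length and library depth) was found in both libraries for 13035 of 55536 annotated genes, of which 11942 were nuclear protein-coding genes. Values are RSEM TPM given as mean ± SD over the 2 libraries, unless stated otherwise.

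Star and Hsd3b1, of steroid synthesis, were among the 10 most abundant nuclear protein-coding genes. Star, which delivers cholesterol to the inner mitochondrial membrane, stood at 1927 ± 242 TPM (SD, n = 2), and Hsd3b1, which makes progesterone from pregnenolone, at 1711 ± 45.0. Cyp21a1, the 21-hydroxylase, reached 1002 ± 42.2 TPM, Cyp11a1, the side-chain cleavage enzyme that opens the pathway, 798.5 ± 51.1, and Cyp11b1, the 11-beta-hydroxylase that completes corticosterone, 632.1 ± 24.5. The 19 genes of the steroid synthesis list took 2.91% ± 0.0748 of the TPM of nuclear protein-coding genes, and all 19 were detected in both libraries. Cyp17a1, the 17-alpha-hydroxylase needed for cortisol and androgens, stood at 3.04 ± 0.304 TPM, and Cyp11b1 exceeded it 209-fold. Electron donors of the cytochromes included ferredoxin Fdx1 at 562.4 ± 23.8 TPM, its reductase Fdxr at 160.5 ± 3.90 and Por at 54.5 ± 5.52. Of the cholesterol supply genes, the lipoprotein receptor Scarb1 reached 525.5 ± 72.6 TPM, the cholesterol esterifying enzyme Soat1 171.5 ± 8.06, the ester hydrolase Lipe 112.4 ± 6.38 and the lysosomal transporter Npc1 20.9 ± 0.629. The ACTH receptor Mc2r stood at 57.0 ± 2.38 TPM and its accessory protein Mrap at 139.4 ± 9.86. The transcription factor Nr5a1, which drives steroidogenic genes, was at 105.8 ± 9.40 TPM and the repressor Nr0b1 at 2.99 ± 0.417. On the mm10 assembly, Star lies on chromosome 8 from 25806555 to 25815982 and Cyp21a1 on chromosome 17 from 34801348 to 34804561.

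Enzymes of the cortical zones differed widely in level. Cyp11b1, the last enzyme of the zona fasciculata pathway, exceeded Cyp11b2, the aldosterone synthase of the zona glomerulosa, by a log2 ratio of 4.07 ± 0.0263 (SD, n = 2), which is 16.8-fold. Cyp11b2 itself stood at 37.6 ± 2.14 TPM. The neighbouring genes lie on chromosome 15, Cyp11b1 from 74834125 to 74841643 and Cyp11b2 from 74851010 to 74856318, and they share long near-identical stretches, so the split of their reads is uncertain. With kallisto the log2 ratio was 3.44, and Cyp11b2 stood at 77.9 TPM. Hsd3b6, the glomerulosa form of 3-beta-hydroxysteroid dehydrogenase, was at 14.7 ± 2.59 TPM, 117-fold below Hsd3b1, and reads of this family are likewise hard to assign. Other glomerulosa genes were the potassium channel Kcnk3 at 184.8 ± 6.22 TPM, Dab2 at 112.8 ± 1.19 and the angiotensin receptor Agtr1a at 62.5 ± 8.63. Akr1b7, an aldose reductase-like enzyme of the fasciculata, was at 824.7 TPM in replicate 1 and 485.98 TPM in replicate 2. Akr1c18, the 20-alpha-hydroxysteroid dehydrogenase that marks the X-zone, an inner cortical layer of young mice, was at 348.2 TPM in replicate 1 and 700.4 TPM in replicate 2. Thrb, a thyroid hormone receptor, was at 13.5 ± 2.35 TPM and Pik3c2g at 1.89 ± 0.962.

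Genes of catecholamine synthesis and storage had a lower median level than the steroid synthesis genes. Pnmt, which converts noradrenaline to adrenaline, stood at 195.1 ± 13.7 TPM (SD, n = 2), Th, the first enzyme of catecholamine synthesis, at 132.0 ± 1.55, and Dbh, which makes noradrenaline, at 97.3 ± 10.2. The log2 ratio of Pnmt to Th was 0.56 ± 0.0846, a 1.48-fold excess of the adrenergic enzyme. Ddc, the decarboxylase, was at 18.1 ± 0.601 TPM and Gch1, which makes the cofactor of Th, at 12.5 ± 1.88. The vesicular monoamine transporters Slc18a1 and Slc18a2 stood at 6.43 ± 0.636 and 5.04 ± 1.15 TPM. Cyb561 was at 38.45 ± 0.226 TPM, and the degrading enzyme Maoa was at 5.84 ± 1.51. Slc6a2, the noradrenaline transporter, was the member with the widest relative spread, at 8.98 TPM in replicate 1 and 3.13 TPM in replicate 2. Granule protein and peptide genes included Chgb at 481.7 ± 37.5 TPM, Chga at 414.4 ± 9.58, Npy at 141.3 ± 12 and Scg2 at 133.2 ± 7. Among the sympathoadrenal transcription factors, Hand2 was at 10.2 ± 0.778 TPM, Gata2 at 8.38 ± 1.83, Phox2a at 7.54 ± 0.849 and Gata3 at 4.88 ± 0.283. The median log2(TPM + 1) of the steroid synthesis list lay 2.88 ± 0.0561 above that of the catecholamine list, a 7.34-fold difference. This difference was larger than its spread between replicates, but it moved with the summary, to 2.42 with list means.

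**Figure D1:**
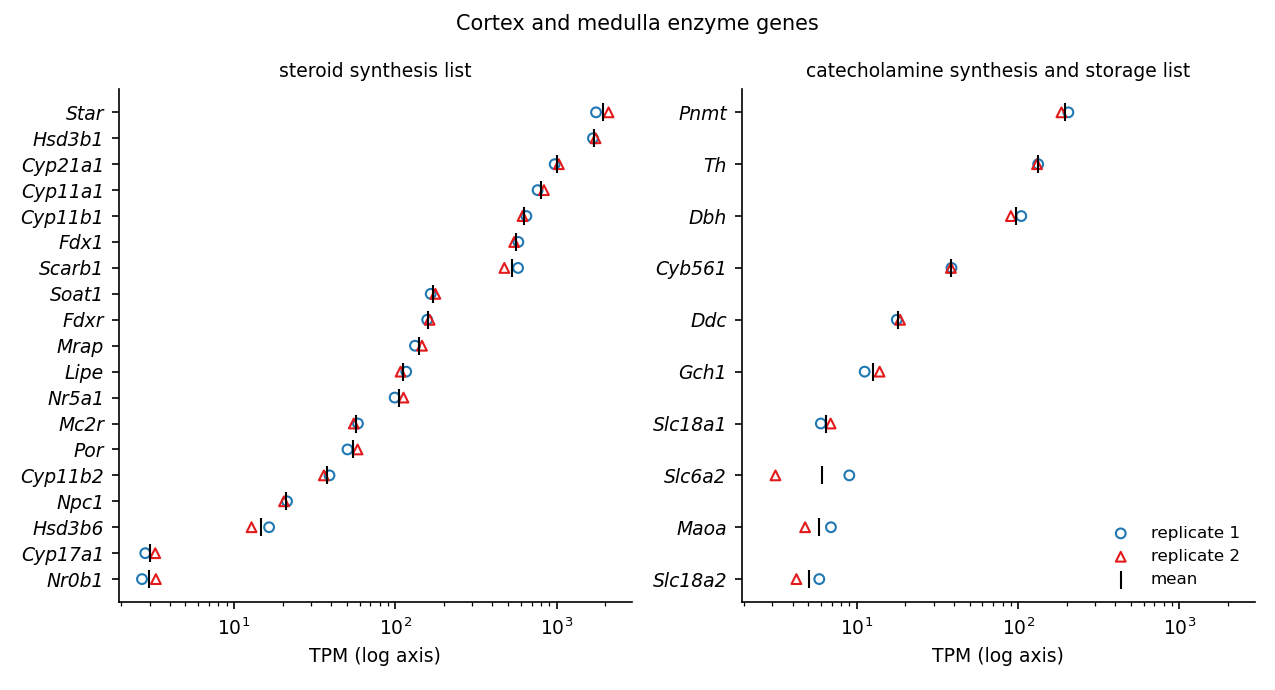
TPM (log axis) of the 19 genes of the steroid synthesis list and 10 of the 11 genes of the catecholamine synthesis and storage list; circles and triangles are the replicate 1 and replicate 2 libraries and bars their mean. Star had the highest mean at 1927 TPM, and Slc6a2 had the widest ratio between libraries, 8.98 against 3.13 TPM.

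All 8 genes of the adipocyte list were detected in both libraries. Fabp4, a fatty acid carrier of adipocytes, stood at 1377 ± 70.8 TPM (SD, n = 2), Ucp1, the uncoupling protein of brown fat, at 792.3 ± 97.2, Cidea at 386.8 ± 12.7 and Plin1 at 183.1 ± 15.6. The list took 1.13% ± 0.00891 of nuclear protein-coding TPM. Whether these transcripts come from the gland itself or from other tissue in the samples was not tested. Blood was represented by Hba-a1 at 2814 ± 462 TPM, Hbb-bs at 2765 ± 595, Hba-a2 at 2572 ± 456 and Hbb-bt at 349.9 ± 43.8, with the split between the near-identical globin copies uncertain. Connective tissue genes included Col3a1 at 179.8 ± 24.1 TPM, Col1a1 at 114.2 ± 24.6, Col1a2 at 87.5 ± 14.2 and Dcn at 60.8 ± 4.27. Endothelial genes included Egfl7 at 62.2 ± 5.14 TPM, Cdh5 at 38.7 ± 2.55, Pecam1 at 35.1 ± 7.66 and Plvap at 31.98 ± 1.09. Glial genes included S100b at 17.6 ± 6.63 TPM, Mbp at 4.20 ± 1.07 and Erbb3 at 1.82 ± 0.905. Macrophage genes included the complement genes C1qa and C1qb at 8.29 ± 0.339 and 8.01 ± 0.601 TPM, and Csf1r at 7.40 ± 2.23. None of the 10 kidney genes reached 1 TPM in both libraries, and the collecting duct channel Aqp2 stood at 0.410 ± 0.0424 TPM. Of the 6 skeletal muscle genes, 1 did, Mylpf at 1.24 ± 0.0990 TPM. The Y-linked genes Ddx3y and Eif2s3y stood at 24.9 ± 1.52 and 22.9 ± 0.226 TPM, Uty at 9.45 ± 0.912 and Kdm5d at 5.20 ± 0.665. Xist, the RNA of the inactive X chromosome, was at 0.140 TPM in replicate 1 and 0.0300 TPM in replicate 2. Zfy1 and Usp9y had no expected counts in either library.

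The libraries held much RNA that carries no poly(A) tail. The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 took 27.9% ± 0.382 of gene counts (SD, n = 2), and protein-coding genes 60.1% ± 0.304. The class with the signal recognition particle RNAs Rn7s1 and Rn7s2 and the polymerase regulator Rn7sk took 4.86% ± 0.266, and genes typed as lincRNA in the annotation 4.225% ± 0.266. Because TPM divides by length, Rn7s1, Rn7s2 and Rn7sk together took 23.6% ± 1.02 of gene TPM, and nuclear protein-coding genes took 27.4% and 27.8% of all TPM in replicates 1 and 2. Rn7s1 and Rn7s2 had identical expected counts in each library, so their reads were split evenly. The most abundant genes typed as lincRNA were Gm26917, at 11324 TPM in replicate 1 and 10266 TPM in replicate 2, and Gm42418, at 2605 ± 149 TPM. Both lie on chromosome 17, Gm26917 from 39843013 to 39846341 and Gm42418 from 39846958 to 39848788. Which RNA their reads come from was not tested, so their type rests on the annotation alone. Malat1, a nuclear RNA of most cells, was at 1855 ± 48.8 TPM, Rmrp, the RNA of a mitochondrial and nucleolar ribonuclease, at 1726 ± 120 in the entry typed as lincRNA, which was at 0 by kallisto in both libraries, and the imprinted Meg3 at 197.5 ± 10.5. Mitochondrially encoded messengers included mt-Atp6, at 14934 and 16399 TPM in replicates 1 and 2, and mt-Co1, at 14683 and 14012; by kallisto mt-Co1 was the higher of the pair in both libraries. The 10 most abundant nuclear protein-coding genes were Hba-a1, Hbb-bs, Hba-a2, Star, Eef1a1, Hsd3b1, Alb, Gnas, Fabp4 and Atp5b, which took 6.96% ± 0.149 of nuclear protein-coding TPM. Alb was among them through replicate 2 alone, at 172.5 TPM in replicate 1 and 3072 TPM in replicate 2. Eef1a1, a translation factor, was at 1914 ± 88.1 TPM, Gnas, the stimulatory G protein subunit, at 1380 ± 55.5 and Atp5b, of the ATP synthase, at 1128 ± 14.4.

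External RNA spike-ins of the ERCC set took 0.311% of expected counts in replicate 1 (95% exact binomial interval 0.309 to 0.312%) and 0.323% in replicate 2 (0.321 to 0.325%). These intervals cover counting error only. Over the 39 spike-ins with at least 10 counts in both libraries, log2 TPM had a Pearson r of 0.997 and a Spearman rho of 0.988 across spike-ins, which are not independent replicates. Their median log2 ratio, replicate 2 over replicate 1, was 0.078, with an SD of 0.265.

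Most nuclear protein-coding genes had close values in the replicates, and groups of liver and lymphoid genes stood apart. Alb, the serum albumin of hepatocytes, was 17.8-fold higher in the replicate 2 library, at 172.5 TPM in replicate 1 and 3072 TPM in replicate 2. Glycam1, a mucin-like ligand made by lymph node venules, had 966 expected counts in replicate 1 and 0 in replicate 2, so it was at least 354-fold higher in replicate 1 against a floor of 3 counts in replicate 2. Of 8314 nuclear protein-coding genes with a mean of at least 5 TPM, 189 were over 2-fold higher in the replicate 2 library and 40 were over 2-fold higher in the replicate 1 library, together 2.75%. The balance depended on the minimum and the quantification: with a mean of at least 1 TPM 422 were higher in replicate 2 and 316 in replicate 1, with at least 20 TPM 67 and 5, and by kallisto 251 and 99. Among the largest ratios were genes that textbooks place in liver: Akr1c6 was 63.2-fold higher in replicate 2, Mettl7b 45.5-fold and Lect2 37.0-fold. Apoc2, an apolipoprotein, had 0 RSEM counts in replicate 1 and 254.3 in replicate 2, but by kallisto it was at 1.13 and 11.8 TPM, a 10.5-fold ratio. Cpb2, a carboxypeptidase of plasma, was 31.7-fold higher in replicate 2, the mannose-binding lectin Mbl2 30.9-fold, Hgd, an enzyme of tyrosine breakdown, 29.8-fold and the cytochrome Cyp1a2 29.8-fold. In the other direction, Ccl21a, a chemokine that draws lymphocytes, was at 44.8 TPM in replicate 1 and 2.38 TPM in replicate 2. The leukocyte genes Cd52, Ltb, Ptprc and Coro1a stood at 20.98, 9.48, 14.7 and 20.8 TPM in replicate 1 and at 2.5, 1.15, 1.92 and 3.24 TPM in replicate 2. The B cell receptor genes Cd79a and Cd79b, at 9.32 and 8.82 TPM in replicate 1, were at 1.63 and 1.48 TPM in replicate 2. Across 12869 protein-coding genes with at least 1 TPM in either library, log2(TPM + 1) had a Pearson r of 0.945 and a Spearman rho of 0.946; genes are not independent replicates. The biological coefficient of variation from the edgeR common dispersion was 0.285 over 16981 genes, and 0.182 with at least 100 counts in both libraries. With a minimum mean of 1 TPM 738 genes differed over 2-fold, with a minimum of 20 TPM 72 did, and with kallisto 350 did.

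**Figure D2:**
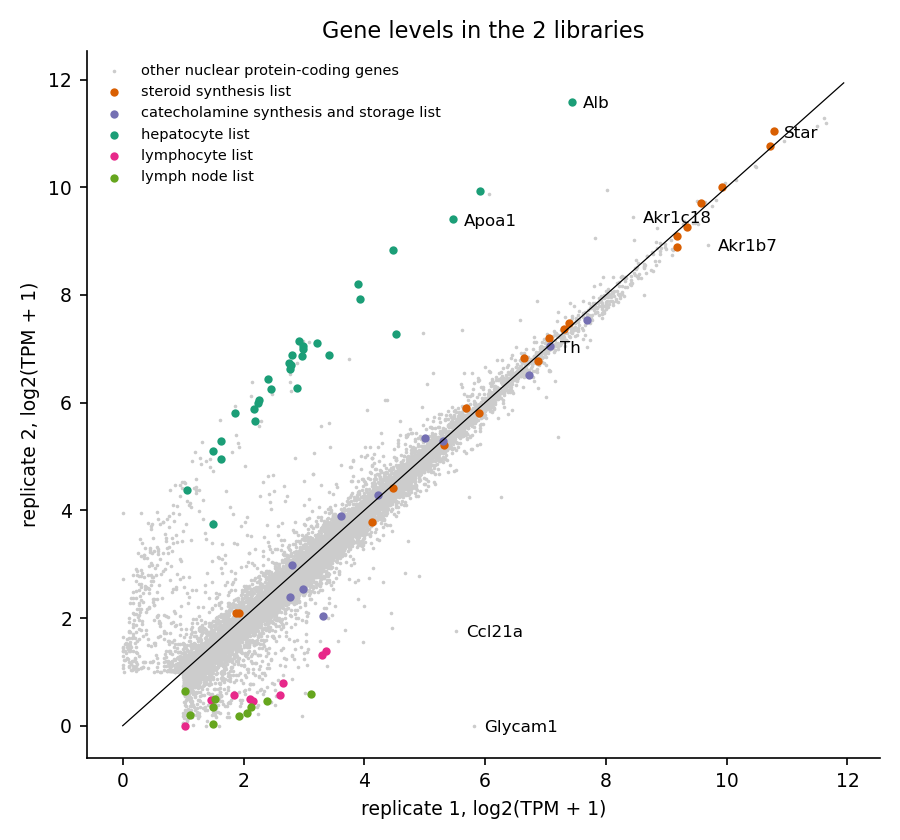
Log2(TPM + 1) of nuclear protein-coding genes in the replicate 1 (x axis) and replicate 2 (y axis) libraries, 1 point per gene with at least 1 TPM in either library; the line marks equal values and colours mark 5 lists, of which the hepatocyte and lymph node lists were added after the data were examined. Steroid genes lie within 2-fold of the line, as do catecholamine genes other than Slc6a2 (8.98 and 3.13 TPM). Alb lies above it at 172.5 and 3072 TPM, and Glycam1 lies at 0 TPM in replicate 2.

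Lists of genes fixed before the data were examined showed which groups set the libraries apart. The detected members of the liver and pancreas list were higher in the replicate 2 library, with a median log2 difference of 3.93 over 5 genes, at percentile 100 among 10000 random lists matched on expression. The 4 liver genes alone had a median of 4.04. The other tested member, the pancreas gene Cela1, was at 6.94 TPM in replicate 1 and 8.87 TPM in replicate 2. Ins2, Gcg and Prss1 had 0 counts in both libraries, and Cpa1 had 0 and 4, so the difference was of the liver genes. Apoa1, the main protein of high-density lipoprotein, was 15.6-fold higher there, Ttr, a thyroid hormone carrier, 21-fold and the protease inhibitor Serpina1a 16.7-fold. The lymphocyte list had a median difference of -1.71, at percentile 0, with 9 of 9 members higher in the replicate 1 library. The T cell receptor complex gene Cd3e stood at 5.09 TPM in replicate 1 and 0.490 TPM in replicate 2.

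Several further groups were higher in the replicate 2 library, the one with the higher liver transcripts (median log2 difference 3.93). All 3 X-zone genes were higher there, with a median difference of 0.69 at percentile 99.7, and Akr1c18 was 2.01-fold higher. The X-zone median lay inside the central 95% of random lists, at percentile 96.7, when the mean was taken in place of the median. Of the 22 genes of cholesterol synthesis and uptake, 19 were higher in replicate 2, with a median of 0.41 at percentile 100; Hmgcs1, Fdps and Msmo1 were 1.43-fold, 1.60-fold and 1.36-fold higher, and Dhcr7 was at 142.5 TPM in replicate 1 and 134.5 TPM in replicate 2. Of the 12 immediate early genes tested, which respond to stimulation within minutes, 11 were higher in replicate 2, with a median of 0.48 at percentile 100. The other 2 of the 14 listed genes, under 1 TPM in both libraries, were lower there. Junb was 3.67-fold higher there, Nr4a1 1.93-fold, Jun 1.41-fold and Egr1 1.41-fold. All 7 heat shock genes were higher in replicate 2, with a median of 0.59 at percentile 100; Hsph1 was 1.85-fold higher, Hspb1 1.53-fold, Hsp90aa1 1.36-fold and Hspa8 1.32-fold. Of 14 proliferation genes 12 were higher in replicate 2, with a median of 0.20 at percentile 100. With the mean in place of the median this list lay inside the central 95%, at percentile 92.9. Top2a was 1.38-fold, Rrm2 1.36-fold, Pcna 1.16-fold and Mcm2 1.13-fold higher.

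The remaining lists were placed in the same way. The steroid synthesis list had a median difference of 0.054 at percentile 97.6, inside the central 95% under 5 of 6 alternative settings, and its sign turned with spike-in scaling, to -0.030. The catecholamine list stood at -0.024 (percentile 64.0), the chromaffin granule list at -0.077 (33.03), the zona fasciculata list at -0.013 (56.4) and the zona glomerulosa list at -0.12 (10.2). With TMM scaling the catecholamine list was at 0.039 and the fasciculata list at 0.051. The sympathoadrenal factors had a median of -0.20 at percentile 8.53, with 9 of 9 tested members lower in replicate 2 by less than 2-fold. Glial genes were at -0.31 (percentile 3.15), capsule and fibroblast genes at -0.16 (4.91), endothelial genes at -0.13 (3.62) and macrophage genes at -0.23 (2.45), the last inside the central 95% under 5 of 6 alternative settings. The glial list left the central 95% with a pseudocount of 0.1 (percentile 1.77) and by kallisto (1.73), and the capsule list with that pseudocount (1.99) and with members of at least 5 TPM (0.11). With the mean the glial list was at -0.049 (percentile 54.7), and 2 of its 7 tested genes were higher in replicate 2, S100b by 1.73-fold and Erbb3 by 2.08-fold. The macrophage gene Lyz2, also made by other myeloid cells, was at 52.0 TPM in replicate 1 and 17.9 TPM in replicate 2. The erythroid list was lower in replicate 2, at -0.34 (percentile 0), but at 0.21 (percentile 82.6) with the mean. The adipocyte list was at 0.073 (94.4), the Y-linked and Xist list at -0.080 (36.2), and the mitochondrially encoded messengers at 0.029 (85.6). With spike-in scaling the adipocyte list was at -0.0096 and the mitochondrial messengers at -0.055. The abundant RNAs without poly(A) tails were at -0.066 (percentile 24.6), but by kallisto at 0.17 (percentile 99.2), outside the central 95%. The kidney and skeletal muscle lists had fewer than 3 members at 1 TPM or more in either library and were not placed. In all, 10 of 25 lists lay outside the central 95% of random lists, and 5 of these did so under every setting tried: cholesterol synthesis and uptake, lymphocyte, liver and pancreas, immediate early and heat shock.

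**Figure D3:**
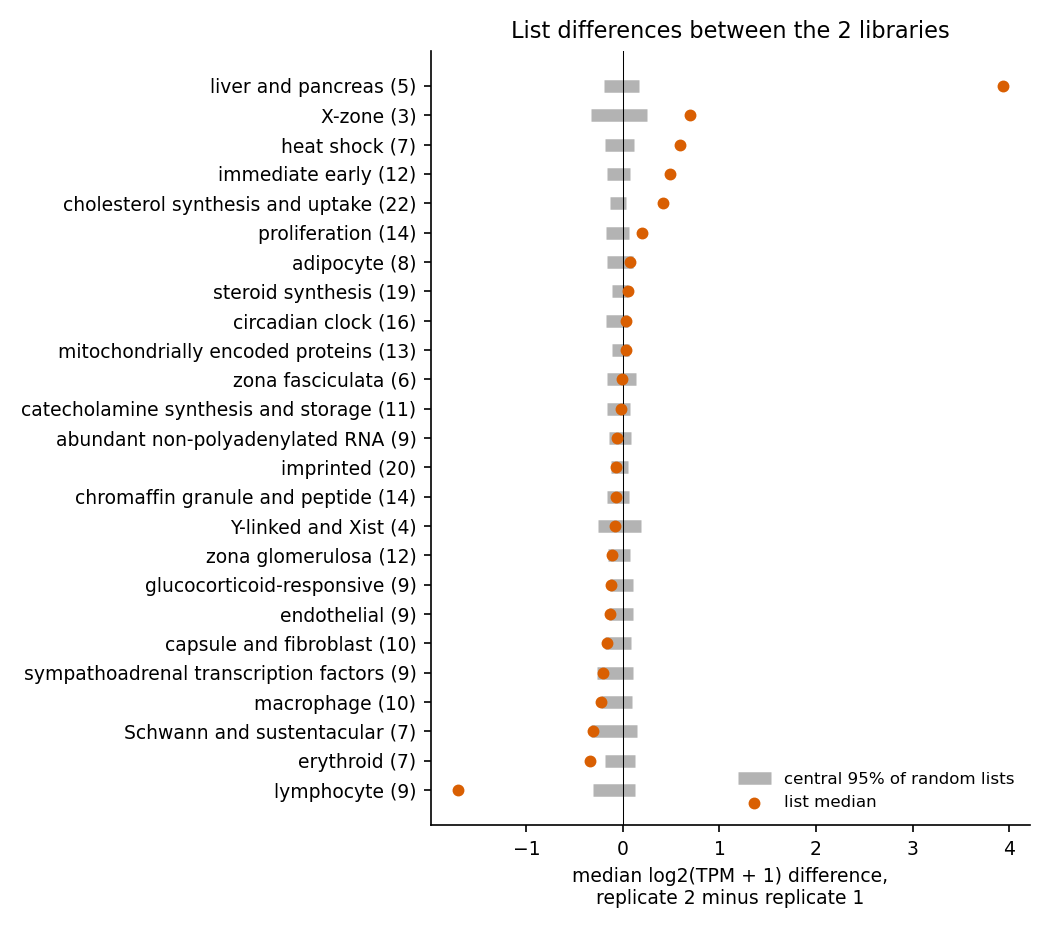
Median difference in log2(TPM + 1), replicate 2 minus replicate 1, of 25 gene lists (points, number of tested genes in brackets) and the central 95% of medians of 10000 random lists matched on expression (bars). The liver and pancreas list lies at 3.93, through its 4 liver genes, and the lymphocyte list at -1.71, while the steroid and catecholamine lists lie near 0.

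The same libraries had been quantified in a second way. Between the RSEM and kallisto values, log2(TPM + 1) had a Pearson r of 0.974 and 0.975 across protein-coding genes in replicates 1 and 2, with Spearman rho of 0.977 and 0.978. Cytochrome c, Cycs, was at 30.2 TPM by RSEM and 428.8 by kallisto, the ribosomal protein genes Rpl5 and Rpl27 at 18.1 and 26.9 against 199.1 and 287.9, the ATP synthase gene Atp5g2 at 11.1 against 196.9 and the histone gene Hist2h2aa1 at 15.3 against 417. Conversely, Rpl10-ps3, Hist2h2aa2, Gm11273, Snurf and Rpl9-ps6 stood at 254.9, 198.8, 47.9, 27.4 and 17.9 TPM by RSEM and at 0 by kallisto. Of 8310 genes with a mean of at least 5 TPM, 845 were over 2-fold higher by kallisto and 30 over 2-fold higher by RSEM, with a median excess of 1.52-fold for kallisto. Nuclear protein-coding genes took 45.9% and 45.5% of kallisto TPM in replicates 1 and 2, and Rn7s1 and Rn7s2 were at 2.35 TPM each by kallisto against 94291 and 90069 TPM in replicates 1 and 2 by RSEM. After rescaling both to nuclear protein-coding genes, 31 genes were over 2-fold higher by kallisto and 66 by RSEM.

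**Figure D4:**
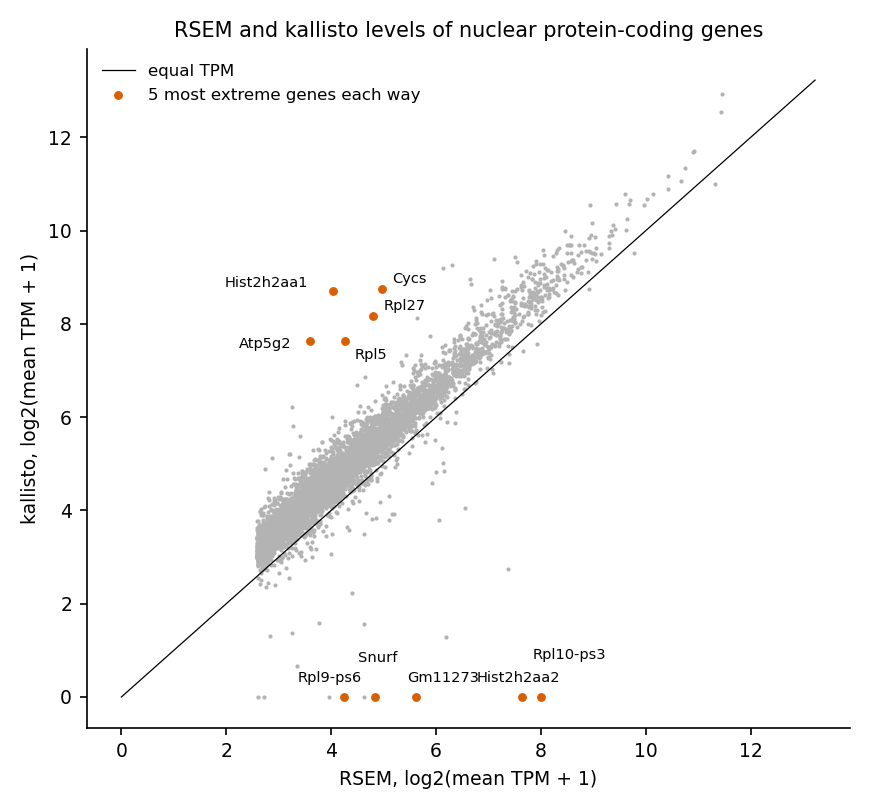
Log2(mean TPM + 1) of nuclear protein-coding genes with a mean of at least 5 TPM by RSEM (x axis) and kallisto (y axis), means over the 2 libraries; the line marks equal values. Most points lie above the line, with a median excess of 1.52-fold, and labelled genes are the 5 most extreme in each direction.

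Single transcripts dominated several of the enzyme genes. By RSEM the top transcript took 97.0% ± 0.0495 (SD, n = 2) of Cyp11a1 TPM, 95.9% ± 0.778 of Cyp21a1, 99.9% ± 0.120 of Pnmt and 99.5% ± 0.778 of Dbh. Star was divided, with 52.0% ± 1.05 on its top transcript, as was Hsd3b1 with 59.6% ± 0.127. Soat1 had its top transcript at 38.1% ± 1.91. Over 30 genes of the steroid and catecholamine lists the RSEM top transcript took a median of 88.2% of gene TPM by RSEM. By kallisto these same transcripts took a median of 82.6%, whether or not kallisto also ranked them top. Both quantifications had the same top transcript for 26 of the 30. The exceptions were Nr5a1, Hsd3b1, Ddc and Slc6a2. Cyp11b1, Cyp11b2, Mc2r, Nr0b1 and Maoa have 1 annotated transcript, so their share of 100% and their match were fixed in advance. For 13 of the 30 genes the share of the RSEM top transcript differed by over 10 points between the quantifications. The RSEM top transcript of Nr5a1 took 78.1% of its TPM by RSEM and 10.1% by kallisto, and that of Ddc 68.2% and 0.156%.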

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

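No test in this part was chosen after its result was seen. The gene tables also list numbered reference entries without a gene name, which no comparison used. In replicate 1 these entries held 6 expected counts in all, above the 3 that a count of 0 allows, and in replicate 2 they held 3. What the entries are was not given in the sources used here, and no explanation was tested.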

How the results depend on the processing

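The gene count without the hepatocyte, lymphocyte and lymph node lists and the X-zone rescaling were chosen only after the data were seen. The lists led with kept their direction under each setting run. Where a value moved, the cause was not tested unless stated.

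With a minimum of 5 TPM 8364 genes were detected, since fewer can pass. The coefficient of variation was 0.334 without a filter and 0.182 with at least 100 counts. The replicate r was 0.915 with a pseudocount of 0.1, 0.962 with 5, and 0.979 with no minimum. The log2 ratio of Cyp11b1 to Cyp11b2 was 3.44 by kallisto. The cortex to medulla difference was 3.34 by kallisto, 2.94 with a pseudocount of 0.1 and 2.42 with list means. The steroid share was 2.73% by kallisto, 0.807% of all genes' TPM, whose larger denominator lowers it, and 3.02% of expected counts. Spike-ins took 0.245% of kallisto counts, and the median share of the RSEM top transcript was 82.6% by kallisto. Genes over 2-fold apart numbered 738 at a minimum of 1 TPM, 72 at 20 TPM and 350 by kallisto. Without the 3 lists named above they numbered 197. Of 112 genes over 8-fold higher in replicate 2, 28 were in the hepatocyte list, so most of these stay in that count. The count of 197 therefore does not measure how many differences come with liver or lymph node transcripts. RSEM and kallisto differed over 2-fold for 390 genes at a minimum of 20 TPM and for 97 after rescaling over nuclear protein-coding genes.

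List medians moved as follows. With a pseudocount of 0.1 they were 1.01 for the X-zone, -2.68 for lymphocytes, 4.04 for liver and pancreas and 0.61 for immediate early genes. With list means they were 3.31 for liver and pancreas, 0.78 for immediate early and 0.80 for heat shock genes. By kallisto they were -1.90 for lymphocytes and 4.10 for liver and pancreas. The cholesterol list was at 0.47 with TMM, 0.34 with spike-in scaling and 0.46 with members of at least 5 TPM, and heat shock at 0.51 with spike-in scaling. The X-zone list was at 0.71 when rescaled without hepatocyte genes. This rescaling changes all genes of a library by the same factor, so it cannot tell whether liver adds to the X-zone genes. Signs turned with spike-in scaling for the steroid (-0.030), adipocyte (-0.0096), clock (-0.025) and mitochondrial messenger (-0.055) lists. They turned with the mean for the erythroid (0.21), glucocorticoid (0.125) and imprinted (0.096) lists, and for the last also with members of at least 5 TPM (0.021). With TMM they turned for the catecholamine (0.039) and fasciculata (0.051) lists, and by kallisto for the RNAs without poly(A) tails (0.17). Of 25 lists, 10 changed side of the central 95% under at least 1 setting.

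Without either replicate, detected genes ranged from 13545 to 13803, the Cyp11b1 to Cyp11b2 ratio from 4.05 to 4.09, Pnmt to Th from 0.50 to 0.62, cortex to medulla from 2.84 to 2.92 and the steroid share from 2.86% to 2.96%. The effect of sequencing depth on genes near 1 TPM was not tested.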

Other observations

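The list and test of lymph node genes were written after the lymphocyte difference and the ratios of Glycam1 and Ccl21a were seen, and before the values of the listed genes were; the tests on hepatocyte genes, scaling, a misassigned liver library, globins, cortex share, related Akr1c genes and liver-borne Akr1c18 were chosen only after the results they bear on were seen. The imprinted list had a median of 20.7 and 23.1 TPM in replicates 1 and 2. Dlk1, a marker of undifferentiated adrenal cells, stood at 137.1 ± 5.32 TPM (SD, n = 2) and the non-coding Rian at 130.8 ± 1.51, while the list as a whole differed between the libraries by a median log2 of -0.069 (percentile 22.7), which turned to 0.096 with the mean and 0.021 with members of at least 5 TPM. H19 was 3.42-fold higher in the replicate 2 library, at 56.1 TPM in replicate 1 and 191.9 TPM in replicate 2, and Igf2, its neighbour in the same imprinted cluster, 1.59-fold higher; both were singled out after their values were seen. The erythroid genes went both ways, with 5 of 7 lower in replicate 2. The globins Hba-a1 and Hbb-bs were 1.26-fold and 1.36-fold higher in replicate 1, whereas the red cell membrane gene Slc4a1, singled out after its values were seen, was 4.20-fold higher in replicate 2.

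Genes that respond to glucocorticoids also went both ways, with a list median of -0.13 (percentile 2.76). The list lay outside the central 95% with members of at least 5 TPM (percentile 2.485), and with the mean its sign turned, to 0.125 (percentile 81.2). Tsc22d3 and Fkbp5, the latter singled out after its values were seen, were each 1.59-fold higher in replicate 1, and Sgk1 was at 49.0 ± 3.15 TPM. The metallothioneins Mt1 and Mt2 were 1.58-fold and 2.54-fold higher in replicate 2. The clock list had a median of 0.037 (percentile 95.5), which was -0.025 with spike-in scaling and, outside the central 95%, 0.098 (percentile 99.7) by kallisto. Of its genes, Per1 stood at 31.4 ± 0.141 TPM, Bhlhe40 was 1.62-fold higher in replicate 2, and Tef was at 26.2 TPM in replicate 1 and 19.3 TPM in replicate 2. Clock was at 12.4 ± 0.311 TPM. Fosb, singled out after its values were seen, was 11-fold higher in replicate 2.

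All 30 genes of the hepatocyte list, 4 of them from the planned liver and pancreas list, were higher in the replicate 2 library, and all 30 also reached 1 TPM in replicate 1. The most abundant were Alb at 172.5 and 3072 TPM, Ahsg at 59.4 and 970.4 TPM and Apoa1 at 43.4 and 676.0 TPM in replicates 1 and 2, and the list took 0.167% and 2.78% of nuclear protein-coding TPM. A factor common to all genes is argued against, because the list had a median difference in log2(TPM + 1) of 3.89. For nuclear protein-coding genes with a mean of at least 5 TPM the median was -0.044. TPM has a fixed total in each library, so this second value alone does not bear on depth. A candidate explanation is liver tissue or liver RNA entering the replicate 2 sample, for which the genes need to move by about 1 factor. The interquartile range of their differences in log2(TPM + 1) was 0.394. The liver genes Akr1c6 and Lect2, named for their large ratios of 63.2-fold and 37.0-fold, were under 1 TPM in replicate 1 and outside this list. The range therefore does not cover such genes. Reads of a liver library assigned to replicate 2 would give the same list median of 3.89 and cannot be told apart, since no liver library was analysed here. No biological explanation was tested, as both libraries are of 1 group.

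The lymphocyte genes, by contrast, were higher in the replicate 1 library. Their median of -1.71 lies far from the -0.044 of nuclear protein-coding genes, which argues against a factor common to all genes. As TPM has a fixed total in each library, the -0.044 alone does not bear on depth. All 4 globins were also higher in replicate 1, so more blood in that sample is not argued against. Their median of -0.35 lies far from the lymphocyte median of -1.71, which argues against blood alone as the account of the lymphocyte difference. Lymph node tissue entering the replicate 1 sample may account for the difference: all 10 genes of the lymph node stroma and follicle list, none of them in the lymphocyte list, were higher there, with a median of -1.61. Of these, Cxcl13 stood at 4.23 and 0.370 TPM and Ccl19 at 3.36 and 0.270 TPM in replicates 1 and 2, and none of the list reached 1 TPM in replicate 2. A difference in lymphocytes within the gland stays open and was not tested.

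Akr1c18 lies on chromosome 13 from 4132615 to 4150654 and was 2.01-fold higher in the replicate 2 library. A larger share of cortex in that sample is argued against. The steroid synthesis genes had a median difference in log2(TPM + 1) of 0.054 and an upper quartile of 0.15. The kallisto log2 ratio of Akr1c18 was 0.97. It cannot decide whether reads are shared with related Akr1c genes, because both quantifications are of the same libraries. Across genes, their replicate log2 ratios had a Pearson r of 0.961. Akr1c18 RNA brought in with liver cannot be told apart from a difference within the gland: its increase in TPM was 12.1% of that of Alb, and no liver library was analysed here to give that share in liver. A larger X-zone in the replicate 2 sample is a hypothesis that stays open and was not tested beyond the list of 3 genes. No biological explanation was given by the design.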
